A study of Mus musculus with 40 samples.

How the data were processed

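Ribosome-bound RNA was measured in 40 immunopurified libraries from the accumbens nucleus of adult Drd1-TRAP CP73 mice. In this line an EGFP-tagged large-subunit ribosomal protein is made under control of the D1 dopamine receptor gene. Pulling down the tag therefore recovers polysomes from cells that express the transgene, mainly D1 medium spiny neurons, the projection neurons of the direct striatal pathway. Per the labels, mice had self-administered saline or cocaine intravenously and were sampled 24 hours or about 1 month later, and the cocaine mice were divided into nonescalating and escalating groups. The labels give 6 groups, and each library was assigned from its own labels. Libraries are named here by group and by the number in their label (1570 to 1609), because replicate numbers repeat within both nonescalating groups.

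The deposited values are whole-number counts of reads per gene symbol, 1 file per library, not normalized. Per the submitters' processing notes, reads were aligned with STAR 2.0.0e to the mm10 mouse genome and counted with HTSeq. The HTSeq version, the gene annotation and the strand setting are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner may therefore not be separable, and counts of near-identical copies, such as ribosomal protein genes with pseudogenes or class I histocompatibility genes, carry that uncertainty. Each file listed 32531 symbols. The 5 closing summary lines and the row named unknown (at most 1 count) name no gene and stayed out of totals and tests. Reads that overlapped no feature made up 18.7% to 70.3% of the uniquely placed reads, and ambiguous reads 1.76% to 4.93%. The ribosomal RNA precursor Rn45s took 2.84% to 17.6% of gene counts. Coordinates came from the GENCODE vM21 annotation of GRCm38, the same assembly as mm10, by symbol. Of 188 different named genes, 182 had a single gene model there.

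Total counts per library lay between 3.77 M and 33.9 M, except for the nonescalating 1-month library 1595 with 5168 counts. Library 1595 stayed in the planned fits and in the planned permutation tests of marker levels (n = 11 for its group). It was left out of the group means ± SD (n = 10), and of the fits and permutation tests as an alternative. Counts of deep libraries within a group were compared pair by pair (122 pairs). The chi-square per gene was 12.8 to 309, so no library of these pairs repeats the counts of the other within sampling noise. Pairs from different groups and library 1595 were not compared. The test cannot show whether libraries come from separate animals. The labels say neither this nor how many animals stand behind a library, so n counts libraries. P-values of single genes and of permutation tests measure the spread between these samples. Those of the gene list test (camera, below) set list members against other genes under a preset correlation, and do not measure that spread.

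Each comparison at 1 time point was fitted with edgeR 4.0.16 under R 4.3.3 over the 20 libraries of that time point, with filterByExpr (minimum count 10), TMM scaling, robust dispersions and the quasi-likelihood F test, two-sided. P-values were adjusted by Benjamini-Hochberg over 14137 genes at 24 hours and 14030 genes at 1 month, with a threshold of 0.05. Numbers of genes given as by chance are 0.05 of the genes tested. They were not taken from other splits of the libraries into groups, which in some comparisons mostly gave more. Pooled cocaine was the mean of the nonescalating and escalating coefficients against saline. The change of each saline contrast from 24 hours to 1 month and the saline time comparison were fitted over all 40 libraries (15555 genes). Standard errors were taken as the log2 fold change divided by the square root of F. Levels are CPM with TMM-scaled totals, given as mean ± SD.

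Of 33 gene lists, 32 had at least 3 tested members and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. List medians and counts of positive members, given beside the camera p-values, are of edgeR log2 fold changes. They can differ in size from the differences in mean log2 CPM, the scale that camera tests. The lists covered immediate early genes; markers of D1, D2 and all medium spiny neurons, striatal interneurons, glutamatergic projection neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, vascular cells, choroid plexus and red blood cells; and dopamine and cAMP signalling, MAPK signalling, glutamate receptors and scaffold, GABA genes, neuropeptides and peptide receptors, voltage-gated ion channels, actin and spine remodelling, synaptic adhesion and perineuronal matrix, chromatin regulators, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, heat shock, unfolded protein response, glucocorticoid-responsive genes, circadian clock, interferon and antigen presentation, cholesterol synthesis, endocannabinoid signalling and oxidative stress. Marker levels per library (mean log2 CPM of a list) were compared between groups with two-sided permutation tests of the mean, exact up to 20000 splits. Correlations of such levels used permutation tests.

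The groups, tests, lists, named genes and most other settings were fixed before the data were examined. The rule named, per pairwise comparison, up to 20 genes with a mean of at least 4 CPM, by smallest p where none passed. It also named 8 genes in every comparison (Drd1, Pdyn, Tac1, Fos, Fosb, Arc, Egr1 and Nr4a1), and up to 4 members of each list past its test. Some list members that met this rule are not reported here; the lists were tested with all members. Clone-named transcripts that met the rule are counted but not named.

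The other settings chosen then were DESeq2-style size factors, DESeq2 1.42.0, limma voom with sample quality weights, no low-count filter, a stricter filter (5 CPM), the replicate number as a block, a glial score as covariate, 1 surrogate variable (sva 3.50.0), leaving out the shallow library, leaving out each library in turn, all 40 libraries in one fit, only the compared groups in the fit, an estimated inter-gene correlation, the self-contained fry test and a prior count of 0.5 for marker levels. Added after seeing the data were fits without the libraries whose median correlation with the others was under 0.8 (1573, 1574 and 1582) and without 1595, a vascular score as covariate, both together with the glial score, and DESeq2 without those libraries.

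The edgeR procedure was tested on simulated counts with 200 changed genes per comparison. Each gene was drawn independently, without correlation between genes and without libraries of a different profile. Recovery and false calls in the real libraries may therefore differ. Of the genes changed 4-fold it recovered 41%, 29% and 31% in the 3 comparisons at 24 hours (nonescalating against saline, escalating against saline, escalating against nonescalating) and 67%, 40% and 53% at 1 month. Of those changed 2-fold it recovered 11%, 3% and 6%, then 30%, 16% and 22%. False calls were 1 of 53, 0 of 32 and 0 of 37 calls at 24 hours, and 6 of 105, 3 of 59 and 1 of 79 at 1 month. DESeq2 made 28 false calls among 105 for nonescalating against saline at 24 hours and 25 among 130 at 1 month, and limma voom 2 among 43 and 7 among 95.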

Results

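The accumbens nucleus was sampled from Drd1-TRAP CP73 mice after long-access intravenous self-administration, in which sessions are long enough for drug intake to escalate in some animals. Ribosome-bound RNA was sequenced in 40 libraries. At 24 hours there were 6 saline libraries (3.77 to 12.9 M counts), 9 nonescalating libraries (9.11 to 15.1 M) and 5 escalating libraries (8.23 to 11.1 M). At about 1 month there were 5 saline libraries (10.5 to 33.9 M), 11 nonescalating libraries (10 of them with 4.97 to 15.2 M) and 4 escalating libraries (5.75 to 6.96 M). Here n counts libraries: replicate numbers repeat within both nonescalating groups, and the labels do not say whether these are separate animals. The nonescalating 1-month library 1595 held 5168 counts and was left out of the group means ± SD given here. It stayed in the planned permutation tests of marker levels. No gene passed an adjusted p of 0.05 in the main edgeR fit of any comparison, while some other edgeR fits did call genes, so the results below rest on gene lists and on levels with their spread.

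The immunopurified libraries held medium spiny neuron markers at high levels, with a median D1 level above the D2 level. The 40 libraries include no input or unbound RNA, so enrichment was not tested. Levels of different lists also depend on which genes they hold. Drd1, the receptor gene behind the transgene (chromosome 13, 54051183 to 54055705), had 443 ± 182 CPM in saline (SD, n = 6), 509 ± 63.8 in nonescalating (SD, n = 9) and 464 ± 66.3 in escalating libraries (SD, n = 5) at 24 hours. At 1 month it had 555 ± 58.2 (SD, n = 5), 524 ± 79.5 (SD, n = 10) and 531 ± 108 CPM (SD, n = 4). The pan-medium spiny neuron markers had a median level of 8.82 log2 CPM over the deep libraries and the D1 markers 6.95, against 5.27 for the D2 markers, 3.75 for vascular cells, 2.30 for astrocytes, 1.70 for oligodendrocytes and -1.10 for microglia. Saline library 1573 (24 hours) stood apart. It had the highest level of the astrocyte (5.04), oligodendrocyte (5.43), oligodendrocyte precursor (4.53), microglia (1.29) and vascular (6.68) markers of all 39 deep libraries and the lowest of the D1 markers (5.19). Of its uniquely placed reads 70.3% overlapped no feature. Its median correlation with the other libraries was 0.751, against a median of 0.907 over the libraries. The correlation of saline library 1574 was 0.693 (51.1% of reads outside features) and that of nonescalating library 1582 was 0.776. Permutation tests of levels covered the cell type marker lists only, not the interferon, ribosomal, channel or other lists. No marker level passed them between groups at a time point, with or without library 1595. With it the vascular difference between nonescalating and saline libraries at 1 month was 0.088 log2 (n = 11 and 5), and 0.63 without it; for D1 markers these were -0.40 and 0.026. In the main setting the smallest p was that of the vascular markers, between escalating and nonescalating libraries at 24 hours. Their difference was 1.28 log2 (exact permutation p = 0.0649, adjusted p = 0.898). With a prior count of 0.5 the exact permutation p was 0.0525 (adjusted p = 0.926). The ranking is not that of the other settings.

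**Figure D1:**
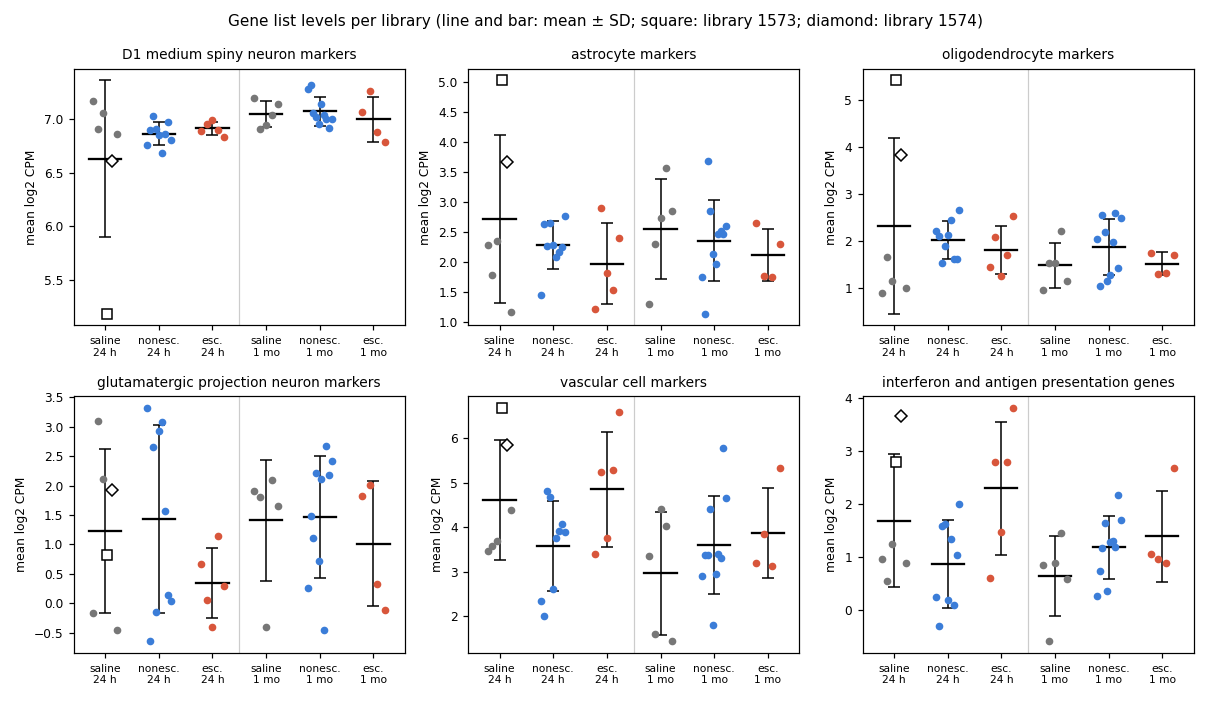
Mean log2 CPM of 6 gene lists in each of the 39 deep libraries, by group and time point; points are libraries, lines and bars mean ± SD, the square is saline library 1573 and the diamond saline library 1574. The D1 level of library 1573 lies at 5.19 and its astrocyte level at 5.04, while the interferon level reaches 3.81 in an escalating library.

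Nonescalating and saline libraries were first compared at 24 hours. Vascular cell markers fell in nonescalating libraries: their mean level was 3.57 ± 1.01 log2 CPM (SD, n = 9) against 4.61 ± 1.35 (SD, n = 6), and 1 of 14 measured members had a positive fold change (limma camera, median -1.57, adjusted p = 3.73e-06, below the saline mean in 7 of 9 libraries). Interferon and antigen presentation genes fell as a list (median of 21 members -1.31, adjusted p = 2.7e-04, 3 positive, 8 of 9 libraries), from 1.68 ± 1.249 log2 CPM (SD, n = 6) to 0.87 ± 0.83 (SD, n = 9). Astrocyte markers (16 members, 3 positive, median -1.04, adjusted p = 0.035) and cytosolic ribosomal proteins (82 members, 10 positive, median -0.34, adjusted p = 9.3e-05) also fell, each in 8 of 9 libraries. The saline means include library 1573, the highest in astrocyte (5.04) and vascular markers (6.68). Counts of libraries below these means therefore depend on it. None of the 4 passed with an estimated correlation (adjusted p = 0.986 with an estimated correlation for each).

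Among single genes of these lists, the vascular member with the smallest p was Vtn, which encodes vitronectin (log2 fold change -2.07 ± 0.59 SE; 18.5 ± 11.5 CPM in nonescalating, n = 9, and 77.8 ± 82.8 in saline, n = 6), followed by the efflux transporter gene Abcb1a (-1.73 ± 0.52). H2-K1, a class I histocompatibility gene (-3.88 ± 1.02), and the immunoproteasome subunit gene Psmb8 (-4.77 ± 1.37) led the interferon list. The glycolytic astrocyte enzyme gene Aldoc (chromosome 11, 78322968 to 78327781; -2.20 ± 0.53) and the glutamate transporter gene Slc1a3 (-2.39 ± 0.61) led the astrocytes, and Rps15 (-1.22 ± 0.41) and Rpl22 (-1.10 ± 0.41) the ribosomal proteins. Adjusted over the list alone, 3 vascular, 4 interferon, 3 astrocyte and 0 ribosomal genes were lower, against 0 over all genes. 4 oligodendrocyte genes, 1 precursor gene and 1 D2 gene were too, in lists that did not pass (adjusted p = 0.146, 0.375 and 0.755). The D2 gene was Drd2, the D2 dopamine receptor gene (chromosome 9, 49340627 to 49408177), at 52.7 ± 18.4 CPM (n = 9) against 136 ± 81.9 (n = 6; -1.36 ± 0.33, adjusted p = 0.195 over all genes with edgeR, below the saline mean in all 9 libraries). All 20 genes with the smallest p were lower (log2 fold change -7.33 to -1.36, adjusted p = 0.195), among them the myelin tight junction gene Cldn11 (-4.86 ± 1.08), Nde1 (-6.54 ± 1.33) and Tcn2, a cobalamin carrier gene (-4.16 ± 0.93). Of these 20, 18 had their highest saline level in library 1574 and 1 in library 1573. Pdyn, the prodynorphin gene of D1 neurons, stood at 448 ± 89.5 against 281 ± 153 CPM (unadjusted p = 0.0285 and adjusted p = 0.416 in edgeR). Saline libraries 1573 (52.1 CPM) and 1574 (140 CPM) had the lowest Pdyn levels, and the other saline libraries had 318 to 445 CPM. The fixed genes ran from -0.30 (Fos) to 0.78 (Nr4a1), with Drd1 at 0.20 ± 0.22.

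The edgeR test called 0 of 14137 genes here, with 1409 at an unadjusted p under 0.05 (707 by chance), DESeq2 called 171 (22 higher, 149 lower) and limma voom 0. With all 40 libraries in one edgeR fit 123 were called (12 higher, 111 lower), with 2464 at an unadjusted p under 0.05. Those 1409 became 417 with limma voom, 469 with the replicate block and 591 with the vascular level as covariate. Without libraries 1573, 1574 and 1582 they became 903 (716 by chance), DESeq2 called 5 (2 higher, 3 lower), and the list medians became 0.00 for vascular (adjusted p = 0.575), 0.10 for interferon (0.963), 0.15 for astrocytes (0.700) and -0.03 for ribosomal genes (0.875). Leaving out 1573 alone turned the ribosomal median to 0.03 (adjusted p = 0.893) and Fos to 0.41. Leaving out 1574 took the interferon median to -0.53 (0.376). The astrocyte call ended without each of 1573 (median -0.14), 1574, 1576, 1578, 1580 and 1581 (medians down to -1.06, adjusted p 0.0514 to 0.893).

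Escalating and saline libraries were compared at 24 hours. Astrocyte markers fell in escalating libraries, from 2.71 ± 1.41 log2 CPM (SD, n = 6) to 1.97 ± 0.68 (SD, n = 5), with 3 of 16 members positive (limma camera, median -1.90, adjusted p = 2.8e-04, lower in 4 of 5 libraries). The saline means of astrocyte and oligodendrocyte markers include library 1573 (5.04 and 5.43), so counts of libraries below them depend on it. Oligodendrocyte markers (15 members, 0 positive, median -1.86, adjusted p = 0.00570, 4 of 5 libraries), striatal interneuron markers (9 members, 0 positive, median -1.34, adjusted p = 0.0417, 4 of 5) and glutamatergic projection neuron markers (8 members, 1 positive, median -1.45, adjusted p = 0.0435, 5 of 5) fell as well. In mean log2 CPM the oligodendrocyte difference was smaller, at -0.53 (exact permutation p = 0.574, adjusted p = 0.898). The levels were 1.80 ± 0.51 in escalating and 2.33 ± 1.87 in saline libraries. Interneuron markers were low, at 0.27 ± 0.52 and 0.62 ± 1.07 (difference -0.35, exact permutation p = 0.533, adjusted p = 0.898), and highest in saline library 1573 (2.22). Glutamatergic markers were low too, at 0.35 ± 0.59 and 1.22 ± 1.39 (difference -0.88, exact permutation p = 0.229, adjusted p = 0.898). Smaller list medians were found for cytosolic ribosomal proteins (-0.29, 14 of 82 positive, adjusted p = 4.1e-04, lower in 4 of 5 libraries), voltage-gated ion channels (-0.19, 14 of 57 positive, adjusted p = 0.0220, 2 of 5) and glutamate receptors and scaffold (-0.15, 13 of 42 positive, adjusted p = 0.0268, 2 of 5). The mean level of the channels was 6.12 ± 0.13 log2 CPM in escalating (SD, n = 5) and 6.11 ± 0.14 in saline libraries (SD, n = 6), and that of the glutamate receptors 5.32 ± 0.42 and 5.34 ± 0.32. With an estimated correlation none of the 7 passed (adjusted p = 0.465 for 5 lists, 0.478 for oligodendrocytes and 0.515 for ribosomal proteins, each with an estimated correlation).

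Slc1a2, the main astrocyte glutamate transporter gene (chromosome 2, 102658659 to 102790784), had the smallest p, with 271 ± 86.4 CPM in escalating (n = 5) and 1060 ± 1067 in saline libraries (n = 6; edgeR log2 fold change -1.99 ± 0.49, adjusted p = 0.953, below the saline mean in 5 of 5). Aldoc stood at -2.30 ± 0.65. Cldn11 (-5.42 ± 1.44) led the oligodendrocyte list, the peptide gene Sst (-2.07 ± 0.65) and the choline transporter gene Slc5a7 (-2.91 ± 1.23) the interneurons. Among the glutamatergic markers the cortical transcription factor gene Neurod2 stood at -5.94 ± 2.50. The postsynaptic scaffold gene Shank1 (-1.65 ± 0.44) and the potassium channel gene Kcnc1 (-0.94 ± 0.28) led their lists. Homer2 (-2.43 ± 0.87) and the calcium channel gene Cacna1c (-0.98 ± 0.36) came next, and Rps15 stood at -1.43 ± 0.49 and Rpl22 at -1.30 ± 0.50. When adjusted over the list alone, 4 astrocyte, 5 oligodendrocyte, 1 interneuron and 1 glutamate receptor gene were lower, and 1 D2 gene (Drd2, -1.53 ± 0.40) in a list that did not pass (adjusted p = 0.0503). Over all genes 0 were. Of the 20 genes with the smallest p, 19 were lower and Zfp568 was higher (4.16 ± 1.18), all at an adjusted p of 0.953, and 17 had their highest saline level in library 1573 or 1574. The 8 fixed genes ran from -1.29 (Fos) to 0.64 (Nr4a1), with Drd1 at 0.05 ± 0.25.

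No adjusted p fell under 0.05 with edgeR: it called 0 genes, with 729 at an unadjusted p under 0.05 (707 by chance), DESeq2 called 9 (4 higher, 5 lower) and limma voom 0. Limma voom had 1145 genes at an unadjusted p under 0.05. All 40 libraries in one edgeR fit gave 0 calls and 1501 at an unadjusted p under 0.05. Without libraries 1573, 1574 and 1582, edgeR called 0 with 1277 at unadjusted p under 0.05 and DESeq2 called 102 (83 higher, 19 lower). There the oligodendrocyte median was 0.55 (adjusted p = 0.0531), the ribosomal median 0.09 (0.896), the astrocyte median -0.12 (0.768), the interneuron median -1.20 (0.0898) and the glutamatergic median -1.36 (0.151). Leaving out 1573 alone ended the astrocyte call (median -0.56, adjusted p = 0.0852), turned the ribosomal median to 0.02 and Drd1 to -0.14, and 1573 (median -0.78) or 1574 (-1.90) ended the oligodendrocyte call. Without 1574 the astrocyte median was -1.24. Drd1 also turned to -0.02 without 1574 or 1585. Other calls ended without each of 1571, 1572, 1573 and 1589 (interneurons, medians -1.71 to -0.93), 1571, 1572, 1573, 1574, 1586, 1587 and 1589 (glutamatergic, -1.70 to -1.13), 1572, 1573, 1575, 1588 and 1589 (glutamate receptors, -0.17 to -0.04), 1572, 1575, 1586 and 1589 (channels, -0.16 to -0.08) and 1589 (ribosomal, -0.21). Without 1588 the glutamatergic median was -2.63, and the glutamate receptor median was -0.23 without 1585 and -0.33 without 1587. In place of 7 lists, 13 passed without 1585, 11 without 1588, 3 without 1572 or 1573 and 2 without 1589.

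Escalating and nonescalating libraries were compared at 24 hours. Interferon and antigen presentation genes rose as a list in escalating libraries, from 0.87 ± 0.83 log2 CPM (SD, n = 9) to 2.29 ± 1.26 (SD, n = 5), with 19 of 21 members positive (limma camera, median 1.29, adjusted p = 6.5e-10, above the nonescalating mean in 4 of 5 libraries). Vascular cell markers rose with them, from 3.57 ± 1.01 (SD, n = 9) to 4.85 ± 1.29 log2 CPM (SD, n = 5), with all 14 members positive (median 1.29, adjusted p = 2.4e-07, 4 of 5 libraries). Glutamatergic projection neuron markers fell (8 members, 0 positive, median -2.00, adjusted p = 0.00506, 5 of 5 libraries). Their levels were low, at 0.35 ± 0.59 log2 CPM in escalating and 1.44 ± 1.60 in nonescalating libraries (difference -1.09, exact permutation p = 0.171, adjusted p = 0.898). None of the 3 passed once the correlation was estimated (adjusted p = 0.223 for interferon and 0.248 for vascular and glutamatergic markers, with an estimated correlation).

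Neuronal lists fell by smaller amounts: voltage-gated ion channels (median -0.22, 7 of 57 positive, adjusted p = 6.5e-05, lower in 5 of 5 libraries) and glutamate receptors and scaffold (-0.22, 7 of 42 positive, adjusted p = 1.5e-04, 3 of 5). Synaptic adhesion and perineuronal matrix (-0.23, 5 of 37 positive, adjusted p = 0.00181, 4 of 5), GABA genes (-0.22, 4 of 21 positive, adjusted p = 0.0122, 3 of 5) and dopamine and cAMP signalling (-0.16, 10 of 39 positive, adjusted p = 0.0167, 4 of 5) fell too. Cholesterol synthesis genes fell as well (-0.29, 6 of 22 positive, adjusted p = 0.00329, 4 of 5 libraries). With an estimated correlation these 6 gave adjusted p = 0.102 (channels), 0.223 (glutamate receptors), 0.312 (GABA) and 0.248 (the other lists). Adjusted over the list alone, 0 genes of any of the 9 lists passed, as over all genes.

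Igtp, an interferon-inducible GTPase gene (chromosome 11, 58199556 to 58207591), had the smallest p: 28.6 ± 39.5 CPM in escalating (n = 5) and 1.34 ± 1.53 in nonescalating libraries (n = 9; edgeR log2 fold change 4.37 ± 0.92, adjusted p = 0.719, above the nonescalating mean in 5 of 5). Its model overlaps that of the related Irgm2 (2.60 ± 0.77), so reads of the pair may not be separable. The guanylate-binding protein gene Gbp5 (3.70 ± 1.03), the noncoding RNAs Neat1 (2.54 ± 0.69) and Gdap10 (3.63 ± 0.80), and the smooth muscle kinase gene Mylk (2.49 ± 0.77) were also among the 20 genes with the smallest p, of which 19 were higher and 1, Olfm1, was lower (-1.27 ± 0.35). H2-K1 (2.66 ± 1.02) and Ifi27 (2.20 ± 0.91) led the interferon list, and Abcb1a (1.59 ± 0.54) and the pericyte receptor gene Pdgfrb (1.88 ± 0.72) the vascular list. Lower members included Neurod2 (-7.11 ± 2.58), Shank1 (-1.02 ± 0.41), Grip1 (-1.40 ± 0.79). Others were the GABA-B receptor gene Gabbr2 (-0.56 ± 0.27), the channel genes Kcna5 (-1.52 ± 0.68) and Kcnn2 (-1.96 ± 0.89), the adhesion gene Cadm3 (-0.48 ± 0.24), Rgs7bp (-0.43 ± 0.23), Rgs14 (-0.97 ± 0.56) and the sterol desaturase gene Sc5d (-1.04 ± 0.52). Members with the opposite sign were Thbs1 (2.87 ± 1.30), Mvk (1.72 ± 0.93) and Gabrd (0.55 ± 0.32). The adjusted p was 1.00 for all these except Igtp and Gdap10 (0.719). The 8 fixed genes ran from -0.99 (Fos) to 0.31 (Arc), with Drd1 at -0.15 ± 0.24.

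With edgeR 0 genes were called, with 446 at an unadjusted p under 0.05 (707 by chance; 265 without 1588, where 12 lists passed, and 276 without 1589, where 6 did), DESeq2 called 3 (Igtp and Gdap10 higher, and Slc30a3 lower, the last chosen after its values were seen) and limma voom called 41, all higher. Limma voom had 1469 genes at an unadjusted p under 0.05, against 446 in the main fit. All 40 libraries in one edgeR fit gave 1 call (Cyr61, higher, chosen after its values were seen). Without libraries 1573, 1574 and 1582 DESeq2 called 33, all higher, the interferon (1.38), vascular (1.41) and glutamatergic (-2.06) calls were kept, as were channels, glutamate receptors, adhesion, GABA and cholesterol, and dopamine and cAMP signalling was not (median -0.13, adjusted p = 0.166). With the vascular level as covariate the interferon median was -0.05 (adjusted p = 0.381), and the GABA (-0.01, 0.665), adhesion (-0.06, 0.227), cAMP (-0.10, 0.262) and cholesterol (-0.28, 0.133) calls ended. Single libraries ended the glutamatergic (1587, median -1.75), GABA (1589, -0.11), adhesion (1589, -0.16) and cAMP calls (1582, 1586 or 1589, -0.14 to -0.11). The vascular median was 0.70 without 1589, the glutamatergic -3.28 without 1588, the GABA -0.14 without 1577 and the cholesterol -0.46 without 1587, and without 1588 Pi16 (3.63 ± 1.15) turned to -0.11 and Arc to -0.01.

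**Figure D2:**
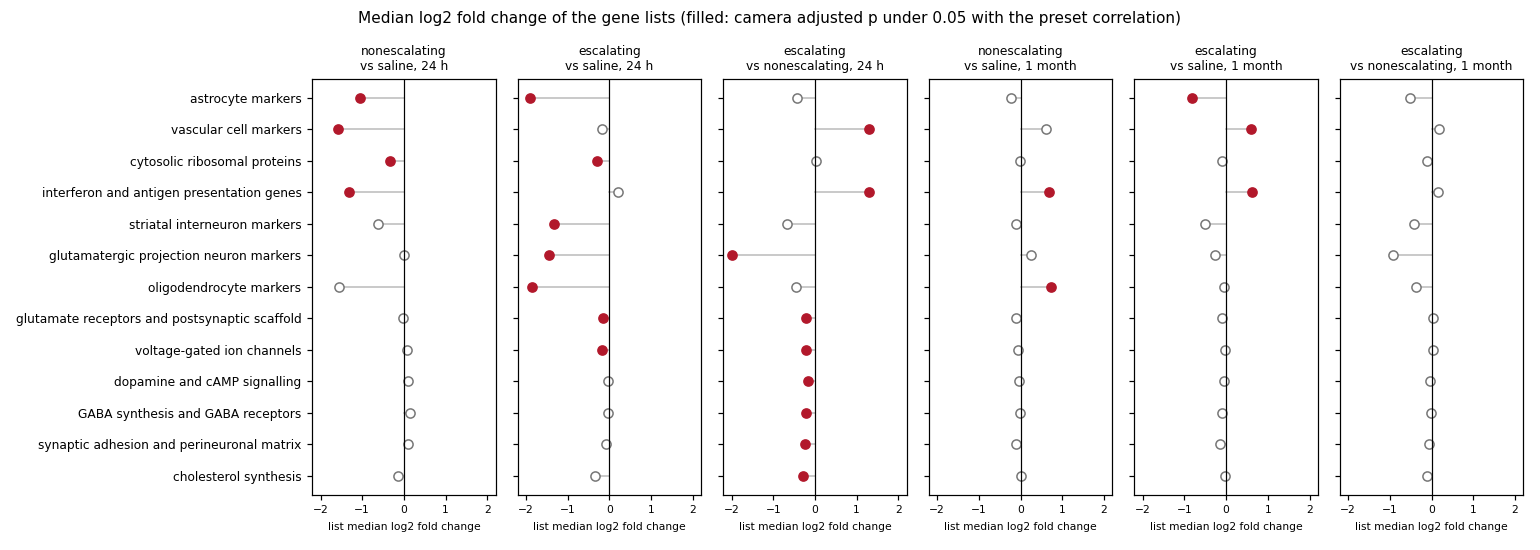
Median log2 fold change of the members of 13 gene lists in the 6 pairwise comparisons; a filled point passed limma camera at an adjusted p under 0.05 with the preset correlation, an open point did not. Interferon and vascular lists reach 1.29 between escalating and nonescalating libraries at 24 hours, against -1.31 and -1.57 between nonescalating and saline libraries.

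Cocaine libraries of both groups were also set against saline at 24 hours, the contrast in the study's design text. Astrocyte markers fell (limma camera, median -1.45, 4 of 16 positive, adjusted p = 0.00108, below the saline mean in 12 of 14 libraries), as did oligodendrocyte markers (-1.54, 0 of 15 positive, adjusted p = 0.0142, 11 of 14). Vascular markers (-0.94, 2 of 14 positive, adjusted p = 0.0132, 9 of 14) and cytosolic ribosomal proteins (-0.33, 11 of 82 positive, adjusted p = 5.8e-05, 12 of 14) fell too. Mean levels were 2.17 ± 0.51 (n = 14) and 2.71 ± 1.41 log2 CPM (n = 6) for astrocytes and 1.94 ± 0.44 and 2.33 ± 1.87 for oligodendrocytes. These saline means include library 1573 (5.04 and 5.43), so the counts of libraries below them depend on it. With an estimated correlation none passed (adjusted p = 0.856 for vascular and 0.791 for the other lists, with an estimated correlation). When adjusted over the list alone, 5 astrocyte and 6 oligodendrocyte genes were lower, and in lists that did not pass 2 interneuron genes, 1 D2 gene and 1 channel gene (adjusted p = 0.203, 0.245 and 0.428), against 0 over all genes.

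The edgeR test called 0 of 14137 genes for pooled cocaine, with 1317 at an unadjusted p under 0.05 (707 by chance) and a smallest adjusted p of 0.103, DESeq2 called 68 (16 higher, 52 lower) and limma voom 0. With all 40 libraries in one edgeR fit 165 were called (3 higher, 162 lower). Leaving out saline library 1570, 1571 or 1572 gave 3, 16 and 37 calls (the 3 were Cldn11, Ext1 and A930011O12Rik, chosen after their values were seen), and leaving out 1574 gave 835 genes at unadjusted p under 0.05. Without 1573, 1574 and 1582 the oligodendrocyte list was called in the opposite direction (median 0.68, adjusted p = 0.0125), while astrocyte (0.01, 0.762), vascular (0.57, 0.454) and ribosomal (0.04, 0.821) calls were lost. DESeq2 then called 55, most of them in the other direction (37 higher, 18 lower). Leaving out 1573 alone ended all 4 calls (astrocytes -0.31, oligodendrocytes -0.45, ribosomal 0.00). 1574 and 1587 each ended the oligodendrocyte call too (down to -1.57), and 1574, 1585 and 1587 the vascular call (medians -0.83 to -0.42).

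About 1 month after self-administration, nonescalating libraries were compared with saline. Interferon and antigen presentation genes rose as a list, from 0.63 ± 0.76 log2 CPM (SD, n = 5) to 1.18 ± 0.60 (SD, n = 10), with 12 of 20 members positive (limma camera, median 0.69, adjusted p = 0.00273, above the saline mean in 8 of 10 libraries). Oligodendrocyte markers rose too (13 of 13 positive, median 0.74, adjusted p = 0.0183, 6 of 10 libraries; 1.88 ± 0.60 against 1.48 ± 0.48 log2 CPM). Neither passed once the correlation was estimated (adjusted p = 0.986 with an estimated correlation for both). Tapbp, which encodes a peptide-loading chaperone (1.37 ± 0.57), and Ifit1 (2.48 ± 1.04) led the interferon list, while Irf7 (-2.38 ± 1.02) and Psmb9 (-2.81 ± 1.27), whose model overlaps that of Tap1, pointed down: Irf7 had 0.603 ± 0.799 CPM (n = 10) and 3.22 ± 5.41 in saline (n = 5). The myelin enzyme gene Cnp (0.84 ± 0.35) and Aspa (2.32 ± 1.17) led the oligodendrocytes. Adjusted over the list alone 0 of either list passed, and 1 precursor gene (higher), 1 glutamate receptor gene and 1 neuropeptide gene (lower) did in lists that did not pass (adjusted p = 0.111, 0.111 and 0.851), against 0 over all genes.

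Of the 20 genes with the smallest p, 9 were higher and 11 lower (adjusted p = 0.900 to 0.982). Limch1 (chromosome 5, 66745827 to 67057158) had 132 ± 18.2 CPM (n = 10) and 89.1 ± 11.6 in saline (n = 5; edgeR log2 fold change 0.58 ± 0.15, adjusted p = 0.900, above the saline mean in 10 of 10). Sidt2 stood at 0.93 ± 0.23, Scarb2 at 1.42 ± 0.41 and the proton pump subunit gene Atp6v0a2 at 0.75 ± 0.20. Npy1r, a neuropeptide Y receptor gene, stood at -1.56 ± 0.40, the guidance cue gene Sema3e at -1.12 ± 0.29 and the AMPA receptor scaffold gene Grip1 at -1.07 ± 0.29. The fixed genes ran from -0.61 (Fos) to 0.14 (Nr4a1, which turned to -0.02 without 1599 and -0.05 without 1604), with Drd1 at -0.09 ± 0.14. No adjusted p fell under 0.05 with edgeR: it called 0 of 14030 genes, with 653 at an unadjusted p under 0.05 (702 by chance), and DESeq2 and limma voom called 0. The interferon call ended without saline library 1591 (median 0.62, adjusted p = 0.267), and the oligodendrocyte call without each of 1590, 1591, 1594, 1596, 1598, 1603 and 1605 (medians 0.58 to 0.79, adjusted p 0.0516 to 0.169). Leaving out the shallow library 1595 gave 5 lists in place of 2, with vascular (higher), glutamate receptor and synaptic adhesion lists (lower) added (adjusted p = 0.0315 for each; 0.812, 0.785 and 0.785 with an estimated correlation). Leaving out 1592 or 1593 gave 4. With the profile outliers and 1595 left out, of which 1595 alone belongs to this time point, DESeq2 called 11 genes (10 higher, 1 lower).

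Escalating libraries were compared with saline at 1 month. Vascular cell markers rose, from 2.97 ± 1.38 log2 CPM (SD, n = 5) to 3.87 ± 1.02 (SD, n = 4), with 13 of 14 members positive (limma camera, median 0.59, adjusted p = 0.00949, 4 of 4 libraries). Interferon and antigen presentation genes rose too (median 0.62, 16 of 20 positive, adjusted p = 0.00843, 4 of 4; 1.39 ± 0.86 against 0.63 ± 0.76 log2 CPM). Astrocyte markers fell (median -0.81, 5 of 16 positive, adjusted p = 0.0463, 3 of 4 libraries). With an estimated correlation none passed (adjusted p = 0.986 with an estimated correlation for each). The endothelial receptor genes Tek (1.10 ± 0.71) and Flt1 (1.03 ± 0.67), the interferon genes Xaf1 (3.34 ± 1.36) and Tapbp (1.46 ± 0.66), and the astrocyte genes Gfap (-4.68 ± 1.68) and Slc1a3 (-0.92 ± 0.42) led their lists. When adjusted over the list alone, 0 genes of these lists passed. 2 precursor genes (higher), 1 MAPK gene (lower) and 1 heat shock gene (higher) did in lists that did not pass (adjusted p = 0.141, 0.788 and 0.788), against 0 over all genes.

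Of the 20 genes with the smallest p, 8 were higher and 12 lower, all with an adjusted p of 1.00. Atp6v0a2 (chromosome 5, 124628576 to 124724455) had 75.8 ± 3.24 CPM in escalating (n = 4) and 39.9 ± 5.30 in saline libraries (n = 5; 0.94 ± 0.24). Sidt2 stood at 1.05 ± 0.28, the heat shock factor gene Hsf1 at 0.76 ± 0.23, the COP9 signalosome gene Cops2 at -0.91 ± 0.23 and the transcription factor gene Etv1 at -0.91 ± 0.25. The fixed genes ran from -0.43 (Fosb) to 0.32 (Pdyn; 564 ± 72.7 against 455 ± 59.8 CPM, higher in 4 of 4 libraries), and Drd1 stood at -0.05 ± 0.17 (0.07 without 1609). With edgeR 0 genes were called, with 585 at an unadjusted p under 0.05 (702 by chance), and DESeq2 and limma voom called 0. The vascular call ended without 1591, 1594 (median 0.35) or 1609 (0.05), the interferon call without 1591 (0.50) or 1609 (-0.03), and the astrocyte call without each of 1591, 1592, 1593, 1594, 1607, 1608 and 1609 (medians -0.92 to -0.46). The vascular median was 0.97 without 1592 and 0.88 without 1608, and the interferon median 1.10 without 1590. Leaving out the shallow library 1595 ended the astrocyte call (adjusted p = 0.0910), and leaving out 1593 gave 6 lists in place of 3.

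Between escalating and nonescalating libraries no list passed its test at 1 month. The glutamate receptor, channel, interferon and vascular lists, called at 24 hours with the preset correlation and not with an estimated one, had no call here. The change of this contrast between time points was not fitted. The lowest list p was that of the astrocyte markers (limma camera, median -0.51, adjusted p = 0.0850). Of the 20 genes with the smallest p, 10 were higher and 10 lower in escalating libraries (edgeR adjusted p = 1.00 for all). The kinase gene Prkx had 19.2 ± 12.4 CPM in escalating (n = 4) and 6.90 ± 3.48 in nonescalating libraries (n = 10; 1.49 ± 0.47), Zfp420 stood at 1.16 ± 0.36, the oligodendrocyte lineage gene Sox10 at 2.70 ± 0.94, Onecut2 at -1.25 ± 0.39 and Etv1 at -0.72 ± 0.23. Pdyn stood at 0.30 ± 0.16 (above the nonescalating mean in 4 of 4 libraries; unadjusted p = 0.0677 and adjusted p = 1.00 in edgeR), Drd1 at 0.04 ± 0.15 (-0.03 without 1607 or 1608) and Arc at -0.28 ± 0.38 (0.01 without 1607). Adjusted over the list alone, 1 precursor gene was higher, in a list that did not pass (adjusted p = 0.979). The edgeR test called 0 genes, with 322 at an unadjusted p under 0.05 (702 by chance; 189 without 1607), and DESeq2 and limma voom called 0. In place of 0 lists, 3 passed without 1600, 2 without each of 1596, 1597, 1601, 1602 and 1606, and 1 without 1607.

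**Figure D3:**
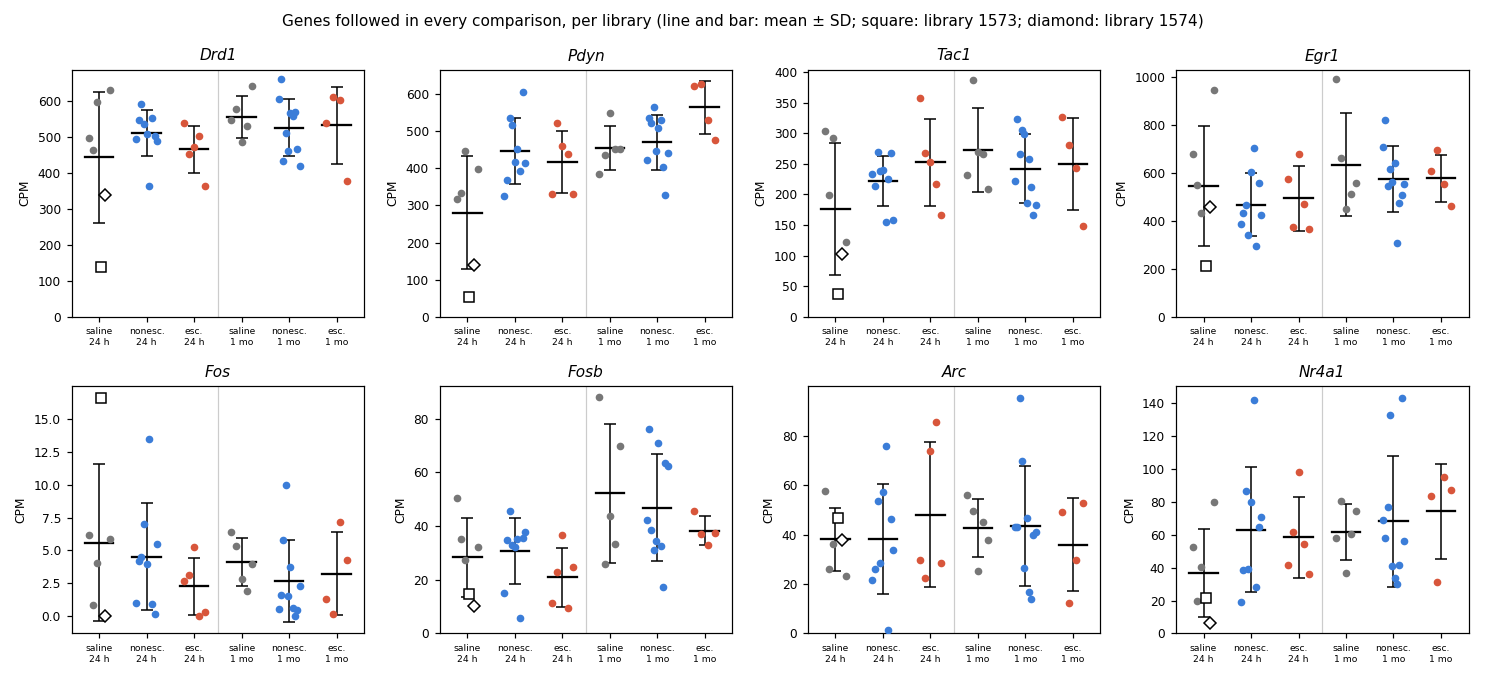
CPM of the 8 genes followed in every comparison in each of the 39 deep libraries, by group and time point; points are libraries, lines and bars mean ± SD, the square is saline library 1573 and the diamond saline library 1574. Drd1 lies at 138 CPM in library 1573, the lowest of the 24-hour saline group, and Fos at 16.6 CPM there, the highest of that group.

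Pooled cocaine was set against saline at 1 month. Interferon and antigen presentation genes (limma camera, median 0.62, 15 of 20 positive, adjusted p = 6.1e-04, above the saline mean in 12 of 14 libraries) and vascular cell markers (0.64, 13 of 14 positive, adjusted p = 0.00955, 11 of 14) rose. Neither passed once the correlation was estimated (adjusted p = 0.998 with an estimated correlation for both). When adjusted over the list alone, 0 genes of either list passed. 1 precursor gene (higher), 1 astrocyte, 1 glutamate receptor and 1 neuropeptide gene (lower) did in lists that did not pass (adjusted p = 0.0910, 0.266, 0.207 and 0.867), against 0 over all genes. No adjusted p fell under 0.05 with edgeR: it called 0 genes, with 679 at an unadjusted p under 0.05 (702 by chance; 1072 without 1596), and DESeq2 and limma voom called 0. The vascular call ended without 1591, 1594 or 1609 (medians 0.25 to 0.54) and was 0.41 without 1604. The interferon call ended without 1591 or 1609 (0.27 to 0.45) and was 0.98 without 1590. Leaving out the shallow library 1595 gave 4 lists in place of 2, with synaptic adhesion (adjusted p = 0.0105) and oxidative phosphorylation (0.0464) lower (0.700 and 0.789 with an estimated correlation). Leaving out 1593 gave 6. With the profile outliers and 1595 left out, of which 1595 alone belongs to this time point, DESeq2 called 3 genes, all higher.

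The difference between time points was tested as an interaction. In the nonescalating contrast against saline, interferon genes (limma camera, median change 1.69, 18 of 22 positive, adjusted p = 1.1e-07), vascular markers (2.11, 13 of 14 positive, adjusted p = 3.3e-06), oligodendrocyte markers (1.999, 14 of 15 positive, adjusted p = 0.00214) and oligodendrocyte precursor markers (3.08, 6 of 7 positive, adjusted p = 0.0102) were higher relative to saline at 1 month than at 24 hours. With an estimated correlation none passed (adjusted p = 0.793 for interferon and precursors and 0.923 for the other lists, with an estimated correlation). In the escalating contrast, oligodendrocyte (1.85, 14 of 15 positive), precursor (2.32, 6 of 7), microglia (1.82, 6 of 9) and vascular markers (0.83, 12 of 14) were higher relative to saline (adjusted p = 0.0276 for each; 1.00 with an estimated correlation). Both contrasts share the saline libraries, whose vascular and oligodendrocyte markers fell. Vascular levels were 4.61 ± 1.35 log2 CPM at 24 hours and 2.97 ± 1.38 at 1 month in saline, 3.57 ± 1.01 and 3.60 ± 1.10 in nonescalating, and 4.85 ± 1.29 and 3.87 ± 1.02 in escalating libraries. Oligodendrocyte levels were 2.33 ± 1.87 and 1.48 ± 0.48 in saline, 2.02 ± 0.40 and 1.88 ± 0.60 in nonescalating, and 1.80 ± 0.51 and 1.52 ± 0.24 in escalating libraries. Adjusted over the list alone, 8 oligodendrocyte, 3 precursor, 2 vascular and 1 interferon gene were higher in the nonescalating change and 1 precursor gene in the escalating change. In lists that did not pass, 1 astrocyte gene and 1 heat shock gene were higher in the first (adjusted p = 0.160 and 0.912), and 2 astrocyte genes and 1 actin gene in the second (0.181 and 0.728). Over all genes 0 were.

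With edgeR 0 of 15555 genes were called for both changes, with 1533 and 762 at an unadjusted p under 0.05 (778 by chance). DESeq2 called 112 (109 higher, 3 lower) and 9, and limma voom 0. Without libraries 1573, 1574, 1582 and 1595 the vascular change of the nonescalating contrast with saline was still called (0.73, adjusted p = 0.0147), and DESeq2 called 17 (12 higher, 5 lower) and 11 (6 higher, 5 lower). The other list calls ended: oligodendrocyte 0.22, precursor 0.57 and interferon 0.39 in the nonescalating change, and oligodendrocyte -0.72, precursor 0.90, microglia -0.21 and vascular -0.76 in the escalating change. In the nonescalating change 1573 or 1574 ended the oligodendrocyte call (1.16 to 1.87) and 1573 the precursor call (1.13), and the interferon change was 0.87 without 1574. Without 1593 there were 7 lists in place of 4. In the escalating change the oligodendrocyte call ended without 1573, 1574, 1585, 1587, 1590, 1594, 1606 or 1609 (0.68 to 1.86), and the precursor call without 1573, 1585, 1587, 1590, 1591, 1594, 1606, 1607, 1608 or 1609 (1.08 to 2.46). The microglia call ended without 1573, 1574, 1585, 1587, 1588, 1590, 1591, 1594, 1606, 1607, 1608 or 1609 (0.21 to 1.97) and the vascular call without 1573, 1574, 1585, 1587, 1591, 1594, 1607 or 1609 (0.29 to 1.00). Microglia stood at 3.58 without 1593 and vascular at 1.29 without 1589. Leaving out the shallow 1595 ended the precursor (adjusted p = 0.0522) and microglia (0.0707) calls of the escalating change.

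The saline groups of both time points were compared as controls; the same libraries enter both changes above with the opposite sign. Time, age and library set coincide and cannot be told apart. Vascular (median -2.01, 1 of 14 positive, adjusted p = 4.0e-09), interferon (-1.63, 3 of 22 positive, adjusted p = 2.5e-06) and oligodendrocyte markers (-2.20, 0 of 15 positive, adjusted p = 5.3e-05) fell at 1 month in all 5 libraries relative to the 24-hour mean. Precursor markers (-2.70, 0 of 7 positive, adjusted p = 0.0155) and red blood cell genes (-1.60, 0 of 3 positive, adjusted p = 0.0227) fell in 4 of 5. None passed once the correlation was estimated (adjusted p = 0.373 with an estimated correlation for each). The counts of libraries are against a 24-hour mean that includes library 1573, so they depend on it. When adjusted over the list alone, 10 vascular, 8 oligodendrocyte, 4 interferon, 2 precursor and 1 red blood cell gene were lower. In lists that did not pass 2 astrocyte genes and 1 D2, 1 actin, 1 adhesion and 1 ribosomal gene were (adjusted p = 0.313, 0.550, 0.932, 0.409 and 0.0654), against 0 over all genes. The edgeR test called 0 genes, with 1998 at an unadjusted p under 0.05 (778 by chance), DESeq2 called 582 (19 higher, 563 lower) and limma voom 0. Other splits of the saline libraries gave 1574 to 3005 genes at that unadjusted p, so 778 understates what a chance split gives. Leaving out 1570, 1571, 1572 or 1575 gave 34, 51, 99 and 11 edgeR calls, and 1 surrogate variable gave 1 (lower). Without 1573, 1574, 1582 and 1595 the vascular median was -0.41 (adjusted p = 0.0164), the oligodendrocyte median 0.10 and the interferon median -0.32, and DESeq2 called 12 (1 higher, 11 lower). The oligodendrocyte and precursor calls ended without 1573 (-1.23 and -1.03), the red blood cell call without 1570, 1573, 1591 or 1594 (-1.47 to -1.11) and without 1595 (adjusted p = 0.0751), and the interferon median was -0.87 without 1574. With DESeq2-style size factors the median of all genes moved by 0.13 and 0.10 in the nonescalating and escalating changes and by -0.13 in the saline comparison, so list medians there are relative to that shift.

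Of the 32 tested lists 16, among them immediate early genes and D1 markers, passed in none of the 11 comparisons in the main fits. The lowest adjusted p of immediate early genes was 0.434 (saline time comparison, median -0.21), of D1 markers 0.193 (saline time, 0.29), of D2 markers 0.0503 (escalating against saline at 24 hours, -0.54). That of pan-medium spiny neuron markers was 0.0751 (escalating against nonescalating at 24 hours, -0.11), of MAPK genes 0.274 (same comparison, -0.03) and of actin genes 0.0751 (same comparison, -0.10). Neuropeptide genes reached 0.0936 (saline time, 0.14), chromatin regulators 0.132 and endocannabinoid genes 0.188 (escalating against saline at 24 hours, -0.16 and -0.42), and circadian clock genes 0.177 (same comparison, 0.22). Oxidative phosphorylation genes reached 0.0860 (escalating against saline at 1 month, -0.18; 0.0464 in pooled cocaine without 1595), glucocorticoid-responsive genes 0.101 (escalating against nonescalating at 24 hours, 0.12), heat shock genes 0.409 and oxidative stress genes 0.676 (saline time, 0.28 and 0.19), unfolded protein response genes 0.541 (nonescalating change, -0.14) and choroid plexus markers 0.639 (escalating change, 0.30). The mitochondrially encoded list had 0 measured genes and gave no test.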

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

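The tests that leave out library 1573 or 1574 for the glial lists, the fits without libraries 1573, 1574, 1582 and 1595, and the vascular covariate, alone or with the glial covariate, were chosen after the results were seen; the other tests below were planned. The nonescalating 1-month group (n = 11) was left out of the screen for single far values. The screened values share libraries, so they are not independent. In 10 of 110 groups of values 1 sample lay far from the others, and chance alone gives about 1 in 20. These values came from 6 libraries, and 4 of them from saline library 1573 at 24 hours: D1 markers at 5.19 log2 CPM (nearest other 6.60), oligodendrocyte precursor markers at 4.53, microglia markers at 1.29 and Fos at 16.6 CPM. The others were D2 markers at 4.47 in nonescalating library 1577, Drd1 at 363 CPM in nonescalating library 1581, glutamatergic markers at -0.40 in saline library 1592, pan-medium spiny neuron markers at 8.72 and interferon genes at 2.67 in escalating library 1609, and a total of 33.9 M counts in saline library 1594.

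A test of the difference between time points called 8 gene lists with the preset correlation. None passed with an estimated correlation (adjusted p = 0.793 to 0.923 in the nonescalating and 1.00 in the escalating contrast). In the nonescalating contrast against saline, oligodendrocyte (1.999), oligodendrocyte precursor (3.08), vascular (2.11) and interferon (1.69) lists were called, and in the escalating contrast oligodendrocyte (1.85), precursor (2.32), microglia (1.82) and vascular (0.83) lists. Both contrasts share the saline libraries, whose mean vascular level was 4.61 log2 CPM at 24 hours and 2.97 at 1 month, so the 8 are not independent. Without libraries 1573, 1574, 1582 and 1595, the vascular change of the nonescalating contrast alone among these 8 was called (0.73, adjusted p = 0.0147).

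The first pattern weighed is the lower level of astrocyte and oligodendrocyte markers in cocaine libraries at 24 hours. Without library 1573 the medians came to 21.4% and 29.3% of their values and neither list was called, which is consistent with a glia-rich saline library as a source of the difference; the library was singled out for its high levels of these lists, so some fall was bound to follow and its size alone was tested. Without library 1574 they came to 69.5% and 101%, so neither fell under the bound set for a cause. The astrocyte call was kept, and the oligodendrocyte call ended at a nearly unchanged median (-1.57 against -1.54). A part played by that library cannot be told apart, because the medians stayed over the bound while 1 call ended. With libraries 1573, 1574 and 1582 left out the oligodendrocyte list was called in the opposite direction (0.68, adjusted p = 0.0125) and the astrocyte median was 0.011 (0.762), so the lower medians were not seen in the other libraries. An effect of cocaine on glial RNA remains open.

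The second pattern is the higher level of interferon genes in escalating than in nonescalating libraries at 24 hours. A single library as the cause is argued against, since the lowest median without 1 escalating library (1589) was 69.3% of its value (0.90, adjusted p = 7.9e-06). That p rests on the preset correlation, and with an estimated one the interferon list was not called. With the vascular level as covariate the median was -3.97% of its value (-0.05, adjusted p = 0.381), which is consistent with more vascular RNA in these libraries as a source. Whether escalation changes vascular content, or the dissection or the pulldown does, was not tested.

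The third pattern is the number of genes at an unadjusted p under 0.05 between nonescalating and saline libraries at 24 hours. It was set against 0.05 of the genes tested, called chance here. Without libraries 1573, 1574 and 1582 there were 903 against 716 by chance, 1.26 times as many. That value lies between the bounds set for a cause and for no cause. The number was under chance with limma voom (417), the replicate block (469), the vascular covariate (591; 707 by chance) and those libraries left out with both covariates (691), and over it in the other alternatives (852 to 3248). These change the model as well as the weight of the libraries. Other splits of the same libraries gave up to 1988 such genes (real 1409), so an excess over such splits was not shown. A source in these libraries, a difference between the groups and a chance split of the libraries cannot be told apart.

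Other splits of the same libraries into groups of the same sizes were counted, the real one included. For gene lists, chance was excluded at a share of 0.05 for escalating against nonescalating libraries at 24 hours alone, where 4 of 100 splits called as many (real 9, highest other 10; 6 without 1589). That share is not corrected for the 11 comparisons, and with an estimated correlation or fry 0 lists passed, so it is weak evidence. Chance was not excluded for the other lists at 24 hours: nonescalating against saline (51 of 100; real 4, highest other 10), escalating against saline (22; 7 and 11) and pooled cocaine (58; 4 and 13). Nor was it at 1 month, for nonescalating (46; 2 and 9) and escalating against saline (48; 3 and 11) and pooled cocaine (52; 2 and 7), nor for the nonescalating change (20 of 60; 4 and 12), the escalating change (35; 4 and 17) and the saline time comparison (25; 5 and 11). Leaving out the shallow library 1595 gave 5 lists for nonescalating against saline and 4 for pooled cocaine at 1 month; splits were not run without it. For escalating against nonescalating at 1 month the real count was 0 (highest other 8), which all 100 splits reach by construction, so nothing follows on chance.

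For genes at an unadjusted p under 0.05 chance was not excluded in any comparison. At 24 hours the counts were 10 of 100 for nonescalating against saline (real 1409, highest other 1988), 96 for escalating against saline (729 and 2188), 49 for escalating against nonescalating (446 and 1150) and 9 for pooled cocaine (1317 and 1971). At 1 month they were 57 (653 and 2113), 16 (585 and 831), 81 (322 and 3040) and 43 (679 and 2014) in the same order. For the nonescalating change they were 5 of 60 (1533 and 1773), for the escalating change 54 (762 and 1921) and for the saline time comparison 22 (1998 and 3005).

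With 0 genes called by edgeR in each real split, all 100 splits (60 for changes and saline time) reach that count by construction, so nothing follows on chance. The highest other counts were 9, 104, 2 and 73 at 24 hours, 31, 0, 437 and 10 at 1 month, 2 and 1 for the changes and 462 for the saline time comparison. Splits that call 437, 462, 104 or 73 genes point to a structure of the samples other than their groups; what it is was not tested.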

How the results depend on the processing

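The fits without libraries 1573, 1574, 1582 and 1595, the vascular covariate, both covariates together and DESeq2 without those libraries were tests chosen after the results were seen; the other alternatives were planned. Over all alternatives, 4900 values of named genes kept their direction and side of the threshold, 68 passed it and 55 turned. None of these genes passed in the main fits, so no call could be lost and the count is no measure of stability. For named lists 926 kept both, 282 lost their call and 31 turned. For list counts 216 stayed within 1.5 times and 90 did not. Where no reason is given below, the cause was not tested. A sex covariate was not run, since all deep libraries express Y-linked genes. Saline library 1573 had the highest level of the X-inactivation RNA Xist (3.84 log2 CPM) beside the highest Y-linked level (4.94). What lies behind this was not tested.

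Gene counts were 0 in the main edgeR fit of every comparison, with 322 to 1998 genes at an unadjusted p under 0.05. DESeq2 called 171 genes for nonescalating against saline at 24 hours, 9 for escalating against saline, 3 for escalating against nonescalating, 68 for pooled cocaine, 112 and 9 for the nonescalating and escalating changes and 582 for the saline time comparison. DESeq2 without the 4 libraries called 5, 102, 33 and 55 at 24 hours in that order, with more higher than lower genes for escalating (83 and 19) and pooled cocaine (37 and 18) against saline, 11 for nonescalating against saline and 3 for pooled cocaine at 1 month (Atp6v0a2, Sidt2 and Trpv4, chosen after their values were seen), 17 and 11 for the changes and 12 for the saline time comparison. The 5 held Kcns1 (higher), Bcar3 and Rslcan18 (lower) and 2 clone-named transcripts, chosen after their values were seen. With all 40 libraries in one fit edgeR called 123 for nonescalating against saline (12 higher, 111 lower), 1 for escalating against nonescalating (Cyr61) and 165 for pooled cocaine at 24 hours (3 higher, 162 lower). Limma voom called 41 for escalating against nonescalating at 24 hours, and 1 surrogate variable 1 for saline time (Rslcan18). Leaving out 1 library gave 0 to 37 for pooled cocaine at 24 hours and 0 to 99 for saline time. On simulated counts DESeq2 made 28 false calls among 105 at 24 hours, edgeR 1 among 53. Those counts held no correlation between genes and no libraries of a different profile, so they do not rank the tools on the real libraries.

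Over all comparisons 44 list tests passed. With an estimated correlation and with fry 0 did, and with the 4 libraries left out and both covariates 4 did, among them glutamate receptors and ion channels between escalating and nonescalating libraries at 24 hours. The estimated correlation of these 44 lay between 0.031 and 0.73, above the preset 0.01 in each, which widens their test. Leaving out 1 library gave 25 (1573) to 59 (1593), and the remaining alternatives 31 to 51. The replicate number as a block gave 45; the median r of libraries with the same number was -0.014 (22 pairs; -0.0058 over 107 other pairs) at 24 hours and 0.018 (20 pairs; -0.0076 over 90 others) at 1 month. With values this near 0 they were not treated as paired. Marker levels per library gave 0 calls in permutation tests in every setting.

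With the 4 libraries left out these medians turned: astrocytes 0.15 (nonescalating against saline at 24 hours) and 0.011 (pooled cocaine), interferon 0.10 (nonescalating against saline), oligodendrocytes 0.55 (escalating against saline), 0.68 (pooled cocaine), -0.72 (escalating change) and 0.10 (saline time), ribosomal proteins 0.095 (escalating against saline) and 0.038 (pooled cocaine), vascular 0.57 (pooled cocaine) and -0.76 (escalating change), and microglia -0.21 (escalating change). Genes that turned there were Drd1 (-0.12 in nonescalating and -0.24 in escalating against saline) and, in nonescalating against saline, Fos (0.23), Psmb8 (0.18) and Slc1a3 (0.27). With DESeq2 they were Drd1 (-0.12 and -0.23), Fos (0.22), Psmb8 (0.18) and Slc1a3 (0.27).

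With the 4 libraries left out and both covariates, interferon turned in nonescalating against saline (0.25) and saline time (0.11), oligodendrocytes in escalating against saline (0.084), pooled cocaine (0.52) and the escalating change (-0.37), ribosomal proteins in nonescalating (0.029), escalating (0.14) and pooled cocaine (0.13) against saline, and vascular markers in escalating against nonescalating (-0.0093) and saline time (0.049). Genes that turned in nonescalating against saline were Fos (0.24), Psmb8 (0.25), Rpl22 (0.021), Rps15 (0.39) and a clone-named transcript (0.82). In escalating against nonescalating they were Arc (-0.29), Gabrd (-0.024), Grip1 (0.40), Kcna5 (0.061), Mvk (-0.51) and Pi16 (-0.16), and in escalating against saline Drd1 (-0.14), with Drd1 (0.0019) and Nr4a1 (-0.083, nonescalating) at 1 month.

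With the vascular covariate, vascular markers (-0.18), interferon genes (-0.051), H2-K1 (-0.051) and Drd1 (0.079) turned in escalating against nonescalating libraries at 24 hours, interferon genes in nonescalating against saline (0.15) and Nr4a1 at 1 month (-0.11). The vascular list itself makes the covariate, so its own loss follows from the construction. With the glial covariate oligodendrocytes turned for pooled cocaine (0.029) and Drd1 in escalating against saline at 24 hours (-0.081). With 1 surrogate variable the vascular list turned for pooled cocaine (0.0037) and Drd1 in escalating against saline (-0.032), and with the replicate block Fos in nonescalating against saline (0.056).

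With limma voom, which gives less weight to libraries with a larger spread, the genes that turned in nonescalating against saline at 24 hours were Cldn11 (1.22), Nde1 (0.54), H2-K1 (0.49), Rps15 (0.067), Vtn (0.021), Fos (0.80) and 2 clone-named transcripts (0.83 and 1.31). In escalating against saline they were Cldn11 (1.16) and Drd1 (-0.16), in escalating against nonescalating Arc (-0.43 at 24 hours, 0.037 at 1 month), and at 1 month Nr4a1 (-0.055).

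Leaving out 1 library moved ribosomal proteins over -0.43 to 0.033 (nonescalating against saline at 24 hours), -0.39 to 0.024 (escalating against saline) and -0.41 to 0.0013 (pooled cocaine), each turned without 1573, and interferon genes in escalating against saline at 1 month over -0.035 (without 1609) to 1.10. Single genes moved over -0.71 to 0.41 (Fos, nonescalating against saline at 24 hours, turned without 1573) and -0.14 to 0.18 (Drd1, escalating against saline at 24 hours, turned without 1573, 1574 or 1585). They moved over -0.11 to 3.96 (Pi16) and -0.0063 to 0.50 (Arc) in escalating against nonescalating at 24 hours, both turned without 1588. At 1 month they moved over -0.053 to 0.25 (Nr4a1, nonescalating against saline at 1 month, turned without 1599 or 1604), -0.13 to 0.070 (Drd1, escalating against saline at 1 month, turned without 1609), and -0.031 to 0.16 (Drd1, turned without 1607 or 1608) and -0.53 to 0.0060 (Arc, turned without 1607) in escalating against nonescalating at 1 month.

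In simulated counts edgeR recovered 29% to 41% of genes changed 4-fold at 24 hours and 40% to 67% at 1 month, so the counts of 0 leave room for changes of that size. Depth as the limit was not tested: between escalating and nonescalating libraries recovery was higher at 1 month (53% against 31%) although their median totals were lower (6.48 and 8.92 M against 8.52 and 10.995 M). The biological coefficient of variation was 0.395 at 1 month and 0.610 at 24 hours.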

Other observations

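No test in this part was chosen before the results were seen: the correlation tests below were added after. Interferon genes and vascular markers rose and fell together over the deep libraries. The mean levels of the 2 lists correlated over all 39 libraries (r = 0.87, rho = 0.80, permutation p = 1e-05, the smallest these permutations can give; adjusted p = 2e-05; r = 0.84 without the 2 farthest libraries), over the 20 libraries at 24 hours (r = 0.90, rho = 0.84) and over the 19 at 1 month (r = 0.85, rho = 0.77). Within the 10 nonescalating libraries at 1 month r was 0.88 (permutation p = 9.7e-04) and 0.74 without the 2 farthest libraries.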
